A study of Caenorhabditis elegans with 2 samples.

How the data were processed

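LIN-11, a LIM homeodomain transcription factor, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in late embryos of Caenorhabditis elegans, labelled 4.25 hours with no starting point for that time given in the sources used here, after synchronisation by egg bleaching. Per the labels, the worms carried an integrated transgene for LIN-11 with a C-terminal GFP and FLAG tag in an unc-119 mutant strain, chromatin was sheared by sonication, and the tagged protein was recovered with an antibody against GFP. The series held 1 group of 2 biological replicates, so no comparison between conditions was possible. Whole embryos of mixed sex were used, so each value is an average over all embryonic cells.

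The authors deposited lists of regions, of which 4 were used: 1 per replicate, 1 from both replicates' alignments together, named here the pooled list, and 1 of regions that passed the irreproducible discovery rate, named here the reproducible regions. Per the deposited notes, all lists are on assembly ce11, the reproducible regions derive from the other 3 lists, and each of those derives from alignments and 1 shared control alignment. The aligner, the peak caller, their versions and their thresholds are not given in the sources used here. Each region has a signal value, which the authors' peak caller assigned relative to that control and whose scale the deposited notes leave open. It was used only to rank or filter regions within a list. The deposited column of −log10 q values reached at most 2.84 and was shared by 350 of the reproducible regions at that maximum, so it was not used for ranking. The deposited summit offset placed each summit within its region. The 560 reproducible regions were tested against the pooled list and all 560 were among its 560 regions of highest signal, so the alternative of taking that many regions from the pooled list was the same set. Read counts and sequencing depth are unknown from these lists, so the intervals given cover counting error over regions or genes only, and a list's length says nothing about binding strength.

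Coordinates and gene models came from the WBcel235 assembly, which is ce11, with Ensembl release 115. RefSeq's annotation of the same assembly supplied sequence and the products of small RNA genes. No region ran beyond a chromosome end. Analyses used the 539 reproducible summits on the 6 nuclear chromosomes, and the 21 mitochondrial regions were set apart. A gene had a summit when one lay within 1000 bp of any of its transcription start sites (TSSs). Among 19973 protein-coding genes, 420 did. Annotation classes were assigned in a fixed order: promoter (within 1000 bp upstream of a protein-coding TSS), coding exon, UTR, intron, other gene, intergenic.

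Shares of summits were compared, two-sided, with 10000 circular shifts of the summits along each chromosome, which keep the spacing of summits; the smallest p they can give is 0.0002. Shares of peaks on chromosome X and in the central part of autosomes were compared by exact binomial tests with the shares of TSSs or genes there. Membership in 23 gene lists, fixed before the data were examined, was tested by Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Odds ratios had 0.5 added to each count. The 9 fixed motifs were sought on both strands within 50 bp of each summit and compared by an exact McNemar test with a window of the same width centred 400 bp away, on a side drawn with a fixed seed, with adjustment over the 9. Exact Clopper-Pearson intervals at 95% accompany shares. The genes named are lin-11 and unc-119, the nearest protein-coding gene of the 12 nuclear peaks of highest signal, up to 4 members of each list that passed an adjusted p of 0.05 and 1 member of each other list, taken by signal. Any other named feature was chosen after its values were seen. The nearest gene was that of the nearest TSS, so a summit could lie within the body of another gene.

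Alternatives set before the data were examined were the higher-signal part of the peaks, the regions of 1 replicate alone, merged overlapping peaks, other windows, other flanks, other references for chromosomes, and other assignments and backgrounds for the lists. For the regions of 1 replicate alone, the nuclear ones among its 560 regions of highest signal were taken. Counts around lin-11 and unc-119 instead used a replicate's whole list. Alternatives added later left out summits at small RNA genes or near lin-11, or took the flank on the other side of each summit. In the circular-shift version of the list test, the odds ratio was used without the added 0.5, because lists with 0 bound members would otherwise have been ranked by the number of bound genes alone. With it added, 12 lists passed, 10 of them with 0 bound members. The tests were tested on simulated data. For the lists, summits were placed near the TSSs of random genes, and were fewer than the 539 of the data. There, the ribosomal protein list was called in 1% of 100 simulations with no enrichment. It was called in 15% with 3-fold and in 63% with 6-fold enrichment over 19973 genes. These rates belong to that setting, since many summits of the data lay away from TSSs. TAATTA planted in 5% of random windows was found in 90% of 100 simulations, and in 4% with none planted. Random windows and their flanks do not differ in GC as the summits and flanks of the data did. That power therefore does not carry over to the data. With 2% of random positions moved to tRNA genes, the excess was found in 100% of 20 simulations, and in 5% with none moved. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.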

Results

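The data describe where GFP-tagged LIN-11 was recovered on chromatin of late C. elegans embryos in 2 biological replicates of 1 strain. LIN-11 is known for its part in the development of vulval cells and of several neuron types. The list of replicate 1 held 21441 regions, that of replicate 2 held 18735 and the pooled list 20692, and 560 regions passed the authors' reproducibility threshold. Those lists of regions and background include many weak entries, so most of what follows concerns the 539 reproducible regions on nuclear chromosomes, with a median width of 430 bp over the 560.

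The first question was how well the replicates placed the same regions. Of the 539 reproducible summits, 469 (87.0%, 95% interval 83.9 to 89.7) lay in the 560 strongest regions of replicate 1 and 438 (81.3%, 77.7 to 84.5) in those of replicate 2. Between the replicates themselves, 389 of 538 nuclear summits of replicate 1's strongest regions (72.3%, 68.3 to 76.0) fell in a strongest region of replicate 2, against a mean of 0.227% for shifted summits (permutation p = 0.002, the smallest that 1000 shifts can give). The reproducible regions were chosen from these same lists, so their recovery is not independent of them. Both lists also rest on the same control alignment, and the shifts do not show how much agreement this alone would give. Across the 535 reproducible peaks listed in both replicates, the ranks by signal had a Spearman's rho of 0.74 (bootstrap 95% interval 0.69 to 0.79), a description across peaks, which are not independent replicates. No region had identical ends in both lists, whose median widths differed (420 and 444 bp), and 75 summits had the same position.

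**Figure D1:**
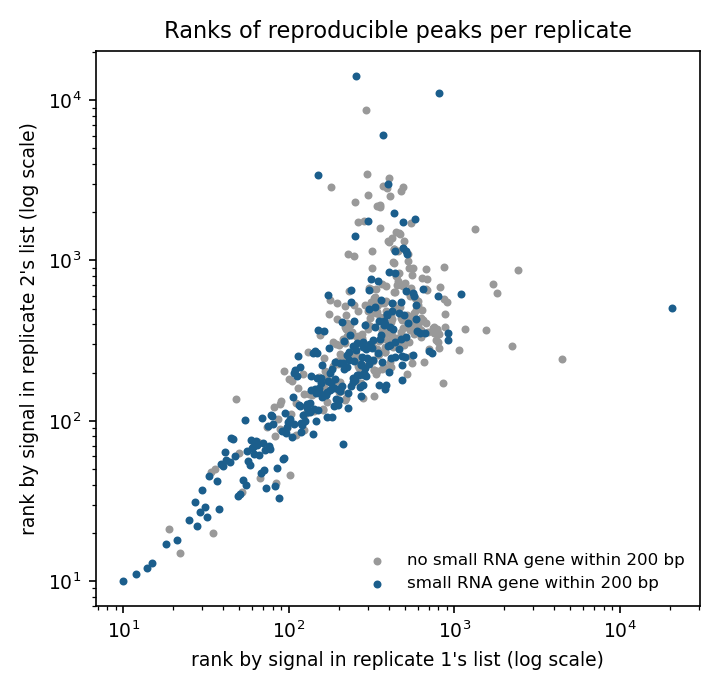
Each point is 1 of 535 reproducible nuclear peaks, placed by its rank by signal in the list of replicate 1 (x axis) and of replicate 2 (y axis), both on log scales, with 1 the strongest and mitochondrial regions counted in the ranks. Points with a small RNA gene within 200 bp of the summit are blue and the others grey. The strongest peaks follow a narrow band, and the overall Spearman's rho is 0.74.

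Reproducible summits lay near the starts of genes more often than shifted summits did. Of the 539, 321 (59.6%, 55.3 to 63.7) were within 1000 bp of a protein-coding TSS, against 40.2% of shifted summits (permutation p = 0.0002, the smallest that the shifts can give). Promoters held 273 summits (50.6%, 46.3 to 54.9, against 21.8%), with 42.3% in the peaks of higher signal and 47.3% and 48.1% with replicate 2 and replicate 1 alone. Genes that do not code for protein held 56 summits (10.4% against 3.16%), while coding exons held 6 (1.11% against 21.2%), UTRs 4 (0.742% against 3.29%) and intergenic sequence 68 (12.6% against 21.8%). These 5 classes passed an adjusted p of 0.05, with 0.0003 in the permutation test for each but UTRs (0.00048). Without summits at small RNA genes, which are themselves among the genes that do not code for protein, that class held 12 of 293 (4.10% against 3.15%, adjusted permutation p = 0.45). Introns held 132 summits (24.5% against 28.8%, adjusted permutation p = 0.036). Without small RNA summits they held 34 of 293 (11.6% against 29.1%, adjusted permutation p = 0.0003), whereas the difference turned around in the peaks of higher signal (30% against 28.8%) and missed the threshold with replicate 1 alone (25.8% against 28.8%, adjusted permutation p = 0.14).

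**Figure D2:**
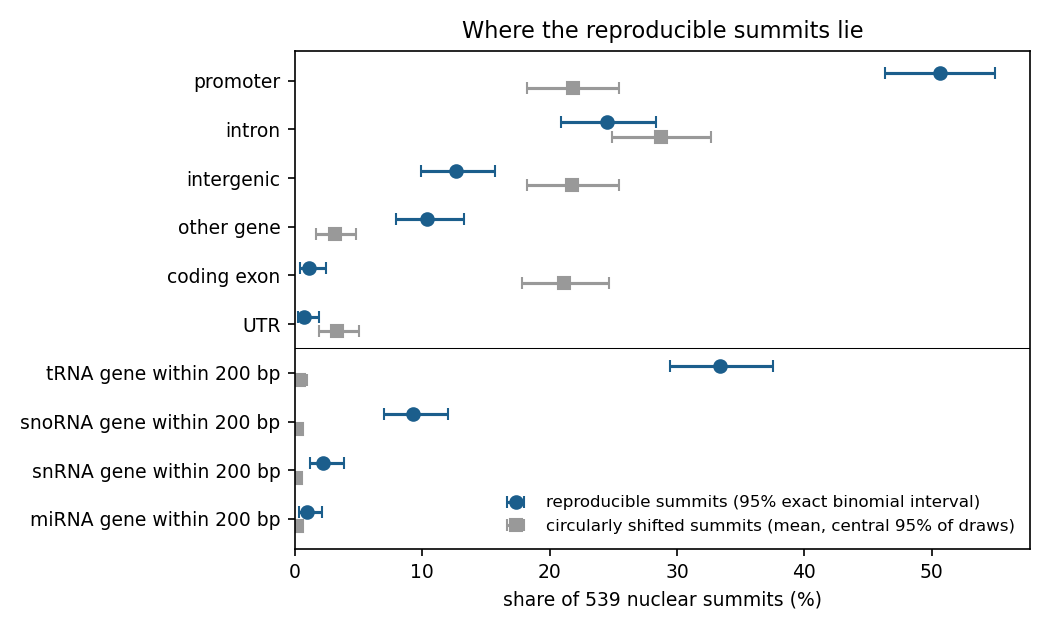
The x axis gives the share in percent of the 539 nuclear reproducible summits in each annotation class (above the line, exclusive classes) and within 200 bp of small RNA genes (below the line). Blue points are observed shares with exact binomial 95% intervals, and grey squares are means of 10000 circular shifts with the central 95% of draws. Promoters reach 50.6% against 21.8% and tRNA genes 33.4% against 0.300%.

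Genes of small noncoding RNAs lay at many summits, above all at those of high signal. Of the 539 summits, 180 (33.4%, 29.4 to 37.6) lay within 200 bp of a tRNA gene, against 0.300% of shifted summits (permutation p = 0.0002). Small nucleolar RNA (snoRNA) genes, whose products guide modification of ribosomal RNA, had 50 summits (9.28% against 0.187%), small nuclear RNA (snRNA) genes of splicing had 12 (2.23% against 0.0570%) and microRNA (miRNA) genes had 5 (0.928% against 0.124%). These 3 classes were tested only after the strongest peaks had been seen, with adjusted p of 0.00033, 0.00033 and 0.0022 over 5 classes. The miRNA call was lost in the peaks of higher signal (2 of 260, adjusted permutation p = 0.11). One summit lay near genes of more than 1 class, so that 11 snRNA summits remain when each summit is counted in 1 class only. No summit lay at the 20 annotated nuclear rRNA genes (0 of 539, upper 95% bound 0.682%). Of shifted summits 0.0153% lay there, so as a share of summits this 0 shows no depletion. Of the 20 genes, 12 have identical copies, and how reads shared between copies were treated is not given in the sources used here. Seen from the genes, 191 of 612 tRNA genes (31.2%, 27.6 to 35.0), 51 of 346 snoRNA genes (14.7%, 11.2 to 18.9), 10 snRNA genes (7.75%, 3.78 to 13.8) and 4 of 261 miRNA genes (1.53%, 0.419 to 3.88) had a summit. Bound tRNA genes spanned the amino acids, from 4 of 19 tRNA-Tyr genes (21.1%, 6.05 to 45.6) to 6 of 13 tRNA-Cys genes (46.2%, 19.2 to 74.9), with overlapping intervals; the only tRNA-Sec gene had none.

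Of the 12 strongest nuclear peaks, 8 lay at snoRNA genes, 1 at a miRNA gene, 1 at a tRNA gene and 2 at no annotated small RNA gene. The strongest (ce11, chromosome II, 11960630 to 11961050, intergenic, signal 1347) lay 61 bp from the snoRNA gene W03C9.9, and its nearest protein-coding TSS, of W03C9.1, was 1291 bp away. The second (chromosome V, 12303444 to 12303875, intronic, signal 1262) covered the snoRNA gene C51F7.4. Its nearest protein-coding TSS, of F55C5.17, was 1101 bp away. The summit lay outside the body of F55C5.17, so the intron was that of another gene. The other snoRNA peaks had as nearest protein-coding genes str-56 and sre-23, both of chemoreceptor families, cutl-18, pxn-1, T02E1.2 and Y43F8C.7. Those of cutl-18, pxn-1 and Y43F8C.7 were intronic. The peak nearest hrg-5 (chromosome IV, 11025883 to 11026380, signal 739) lay 85 bp from the microRNA gene cel-mir-51, and that nearest C04A11.5 (chromosome X, 13665403 to 13665782, signal 657) covered a tRNA-Leu gene. The 2 without a small RNA gene lay in the promoter of K12H4.5 (chromosome III, 8043787 to 8044140, 526 bp upstream, signal 875) and 4967 bp upstream of nas-30 in intergenic sequence (chromosome I, 933362 to 933674, signal 774). All 12 ranked between 10 and 31 in both replicates, where mitochondrial regions were counted.

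Peaks of higher signal were at small RNA genes more often than peaks of lower signal. In the strongest 134 peaks, 98 summits (73.1%, 64.8 to 80.4) were within 200 bp of such a gene, against 32 of the weakest 134 (23.9%, 16.9 to 32.0; Fisher's exact test, p = 4.9e-16, a test added after the data were seen). The share within 1000 bp of a protein-coding TSS went the other way, at 66 of 134 (49.3%, 40.5 to 58.0) in the strongest and 88 of 134 (65.7%, 57.0 to 73.7) in the weakest (Fisher's exact test, p = 0.0093). That difference missed the threshold with the regions of replicate 2 alone (exact p = 0.087), within the peaks of higher signal (0.078) and when all peaks were split at the median (0.053), and changed direction without small RNA summits (exact p = 0.13). TAATTA, taken here as the core of LIM homeodomain sites, was within 50 bp of 0 and 1 of these summits (exact p = 1).

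**Figure D3:**
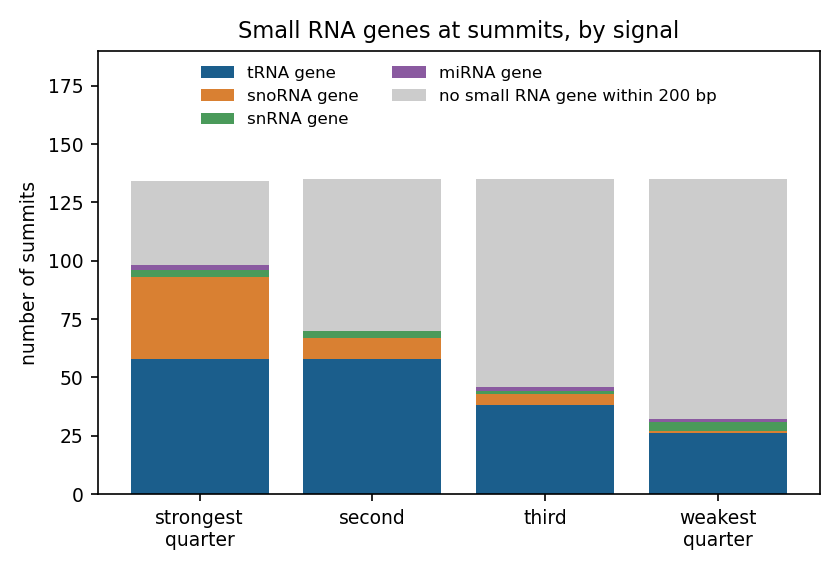
Bars give the number of summits (y axis) in 4 groups of nuclear reproducible peaks ordered by the authors' signal (x axis, strongest at the left), stacked by the class of small RNA gene within 200 bp. Summits with no such gene number 36, 65, 89 and 103 from the strongest to the weakest group.

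Chromosome X carried more peaks than its share of start sites. It held 124 of 539 summits (23.01%, 19.5 to 26.8) against 14.04% of protein-coding TSSs (exact binomial test, p = 2.6e-08). Of the 612 tRNA genes, 276 are on X, and 79 of the 180 tRNA summits were there (43.9%, 36.5 to 51.5). A summit was at 85 of the 276 X-linked tRNA genes (30.8%, 25.4 to 36.6) against 106 of the 336 autosomal ones (31.5%, 26.6 to 36.8) (Fisher's exact test, p = 0.86). None of the 50 snoRNA summits was on X (upper bound 7.11%), where 33 of the 346 snoRNA genes lie. Without small RNA summits, 45 of 293 (15.4%, 11.4 to 20.01) were on X (exact binomial p = 0.50, added after the data were seen). Along the autosomes, 158 of 415 summits (38.1%, 33.4 to 42.9) were in the central part of the chromosome, of 33.3% of its length, which holds 38.1% of autosomal protein-coding genes (exact binomial p = 1).

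The genes near summits were tested for the functions fixed in advance. Genes of ribosomal proteins had a summit at their start more often than other genes, at 10 of 79 (12.7%, 6.24 to 22.05) against 2.06% (odds ratio 7.17, Fisher's exact test with Benjamini-Hochberg adjustment over 23 lists, adjusted p = 6.9e-05). The strongest were at rpl-3 (chromosome III, region 3867451 to 3867704, signal 286, 278 bp upstream), rps-20, rpl-20 and rps-19, with signals of 286 to 211, all in promoters. Chaperones followed, with 5 of 50 heat shock genes (10%, 3.33 to 21.8, odds ratio 5.68, adjusted exact p = 0.030). Among them were the DNAJ co-chaperones dnj-29 (chromosome I, 14113143 to 14113390, signal 348), dnj-9 and dnj-5 and the mitochondrial chaperonin hsp-60. The dnj-5 summit ranked 511, and 1323 and 1567 in replicates 1 and 2, outside the 560 strongest regions of both. Chemoreceptor genes had fewer, at 5 of 1232 (0.406%, 0.132 to 0.945) against 2.21% (odds ratio 0.198, adjusted exact p = 1.3e-05). The summits of sre-23 and srh-269 lay at a snoRNA and a tRNA gene, while those of sre-1 and sri-5 did not. All 10 ribosomal protein genes and all 5 chaperone genes had no small RNA gene within 200 bp of their strongest summit. A summit counted for a gene could lie nearer to the start of another gene. Examples are the summits of rps-20 (152 bp from ekl-4), hsp-60 (231 bp from Y22D7AL.10) and sre-1 (77 bp from B0495.9).

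These 3 calls depended on the background and other settings. Among genes with a pooled-list region at their start, no list passed and 2 had an unadjusted p under 0.05. There, summits were at 10 of 65 ribosomal protein genes against 5.32% (adjusted exact p = 0.054), 5 of 36 chaperone genes (0.49) and 5 of 196 chemoreceptor genes (0.60). With shifts that keep neighbouring genes together, ribosomal proteins passed (adjusted permutation p = 0.014), but chemoreceptors (0.083) and chaperones (0.34) did not. Chaperones passed in 4 of 11 alternatives and also missed with replicate 1 alone (3 of 50, adjusted exact p = 0.62), in the peaks of higher signal (0.12) and with windows of 500 bp (0.31) or 2000 bp (0.090). Chemoreceptors missed in the peaks of higher signal (adjusted exact p = 0.15), and both ribosomal proteins and chaperones missed when each summit was given to its nearest TSS only (0.058 each).

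Lists tied to the known roles of LIN-11 did not pass. LIM homeobox genes had 1 of 7 bound, lin-11 itself (adjusted exact p = 0.53), homeobox genes 2 of 98 (lin-11 the strongest, adjusted p = 1) and vulva and uterus genes 2 of 30 (6.67%, 0.818 to 22.1, adjusted p = 0.53), led by egl-17, an FGF-like factor, whose summit lay at a tRNA gene. The other of these 2 was lin-11 itself, and leaving out either the summits around lin-11 or those at small RNA genes left 1 of 30. No summit was at the 28 pan-neuronal genes (upper bound 12.3%), 17 neurotransmitter pathway genes (19.5%), 37 axon guidance genes (9.49%), 46 cilia genes (7.71%) or 11 genes of neurons known to express lin-11 (28.5%), nor at bHLH (39), pharynx (25), intestine (48), Wnt and Notch (36) or histone (50) genes. Some of these were not 0 with the regions of 1 replicate: replicate 2 alone had summits at 3 of 50 histone genes (6%, adjusted exact p = 0.45), 1 of 39 bHLH and 1 of 37 axon guidance genes, and replicate 1 alone at 1 of 28 pan-neuronal genes (adjusted exact p = 1 for these 3 lists). Neuropeptide genes had 2 of 144 (flp-23 strongest), nuclear hormone receptors 2 of 274 (nhr-255), epidermis and cuticle genes 3 of 204 (col-85), body wall muscle genes 1 of 41 (unc-60), germline genes 1 of 50 (mex-1), proteasome genes 1 of 33 (rpn-7) and mitochondrial respiration genes 2 of 41 (nuo-2). The strongest summits of flp-23, nhr-255 and col-85 lay at tRNA genes. That of unc-60 ranked 292 in replicate 1 and 8669 in replicate 2, outside the 560 strongest regions of replicate 2. Those strongest regions had summits at 0 of 41 body wall muscle genes. The power of the test was simulated for the ribosomal protein list alone, not for these lists.

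TAATTA was rare at summits, and shorter forms of the homeodomain site were not counted. TAATTA was within 50 bp of 9 of 539 summits (1.67%, 0.766 to 3.15) and of 32 flanks (5.94%), an exact McNemar p of 0.00043 (adjusted p = 0.0013 over 9 motifs). Summit windows had 49.5% GC and flanks 35.97%, and among the 14 hexamers of 3 A and 3 T the ratio of TAATTA ranked 6 from the lowest, so its scarcity was not set apart from that of hexamers of the same composition. Without small RNA summits it was at 7 summits and 16 flanks of 293 (adjusted exact p = 0.21). TAATTG (11 against 46, adjusted exact p = 1.5e-05) and TGATAA, a GATA factor site (18 against 44, adjusted p = 0.0019), were also rarer at summits. With replicate 2 alone, TAATTG was at 16 summits against 33 flanks (adjusted exact p = 0.031). Neither motif was compared with hexamers of its composition, so their scarcity was not set apart from the difference in GC. Without small RNA summits both missed the threshold, TAATTG at 8 against 20 (adjusted exact p = 0.11) and TGATAA at 9 against 23 (0.073). GAGAGA was more frequent, at 78 summits (14.5%, 11.6 to 17.7) against 29 flanks (adjusted exact p = 1.0e-05), but missed the threshold in the peaks of higher signal (11.2% against 6.15%, adjusted p = 0.16). It was not compared with hexamers of its composition either, so its excess was not set apart from the difference in GC. CACGTG, CAGCTG, TGACTCA, TGTTTA and ATGCAAAT did not pass (adjusted p of 0.13 to 1), though TGTTTA did with the flank on the other side (26 summits against 46 flanks, adjusted exact p = 0.044).

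The gene that was tagged stood out by its own surroundings. Within 20 kb of lin-11 (WBGene00003000, chromosome I, 10248288 to 10255327, plus strand) lay 5 reproducible regions, the highest number around any of the 19973 protein-coding genes and reached at no other, and 23 regions of the pooled list, more than around 99.1% of genes (median 8). Within 10 kb there were 12 pooled-list regions, more than around 96.6% of genes (median 4). The strongest of the 5 (10235115 to 10235544, signal 437, rank 52) had its summit 12958 bp upstream of the lin-11 TSS in a noncoding gene, nearest to csnk-1. One covered the lin-11 start (10248060 to 10248489, summit 13 bp upstream, signal 179) and one lay in a lin-11 intron (10252584 to 10253013, signal 217). The others were intergenic upstream (10237200 to 10237629, signal 135) and in an intron of ZC247.2 downstream (10260130 to 10260559, signal 195). The upstream one at signal 135 ranked 390 in replicate 1 and 2844 in replicate 2, whereas the other 4 ranked between 46 and 327 in both. Around unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935, plus strand), the gene mutated in the strain, there were 0 reproducible regions and 12 pooled-list regions, more than around 76.6% of genes. In the whole list of replicate 2 there were 7, the median, more than around 43% of genes. Percentiles here describe these lists and no test was made.

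**Figure D4:**
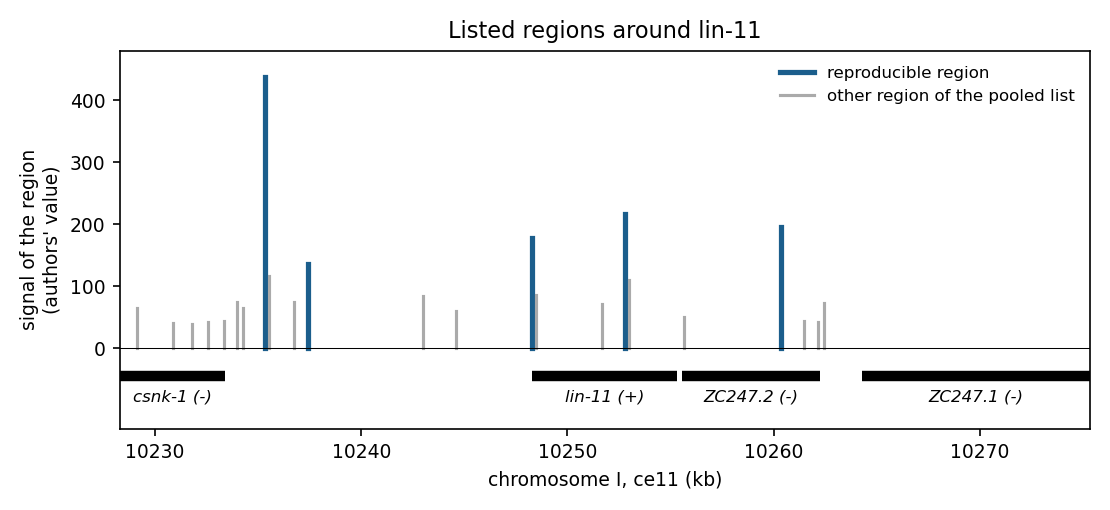
The x axis is chromosome I of ce11 in kb, from 20 kb before to 20 kb after lin-11, and each vertical line is a pooled-list region at its summit, with the authors' signal on the y axis. Blue lines are the 5 reproducible regions and grey lines the other 18, and black bars under the axis are protein-coding genes with their strand. The 5 reproducible regions reach signals of 135 to 437.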

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

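Tests on nuclear summits left out the mitochondrial genome, whereas ranks by signal in each replicate counted its regions. It held 21 of the 560 reproducible regions. They are flagged because this is more than the 3 that a count of 0 allows, a rule for flagging that does not say how many to expect, which was not tested. They overlapped in 3 distinct intervals that covered 12953 of 13794 bp (93.9%), took 8 of the 10 highest signals of the whole list and included the highest (4108), and the lists of replicate 1 and 2 held 22 and 21 regions there.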

How the results depend on the processing

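Of 463 values under an alternative setting, leaving out the set from the pooled list, which is the same regions, 428 kept their direction and side of the threshold, or stayed within their interval or within 1.5 times the count. Of the 35 that did not, 20 concern single classes, lists or motifs. Leaving out small RNA summits or the surroundings of lin-11, and taking the flank on the other side, were chosen after seeing the data. Except where stated, the cause was not tested. The shares near a TSS, in promoters and at tRNA genes kept their direction and their side of the threshold under every alternative run for them, from 44.7% to 76.1% near a TSS and from 31.8% to 43.8% at tRNA genes.

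Recovery of reproducible summits moved with the rule for a match: under a reciprocal overlap of 50% it was 80.5% in replicate 1 and 68.8% in replicate 2, and in lists of 1120 regions, where by construction more can match, 97.8% and 92.0%. The share of autosomal summits in the central part, 38.1%, lay above that part's 33.3% of length (exact binomial p = 0.042) but not above its share of genes. Introns held 30% of summits of higher signal. Without small RNA summits, 15.4% of summits were on X and 2.39% had TAATTA, neither past the threshold with 293 summits. The number of lists past the threshold, 3, became 1 in the highest-signal part of the peaks, 1 with the nearest TSS only, 1 with circular shifts of the summits and 0 among genes with a region of the pooled list. For the strongest against the weakest peaks, the share near a TSS differed by -16.4 percentage points in the report, past the threshold. It differed by -16.9 in the highest-signal part, by -8.55 when all peaks were split at the median and by 12.3 without small RNA summits, none of these 3 past it; with the regions of 1 replicate alone it ranged from -13.4 to -11.1, the latter, from replicate 2 alone, not past it.

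Recovery and rank correlation need both replicates, so neither was computed without one. No paired analysis was possible because the series held 1 group. Depth is unknown from these lists, so whether more reads would add regions at neuronal or vulval genes cannot be seen here.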

Other observations

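In this part, the tests of identical copies and of GC content were written before their results were seen; those of TAATTA, of the B box, of all hexamers and of the surroundings of lin-11 were chosen after. The TAATTA test was changed after its values were seen, first from summits against flanks, to the same against matched hexamers, then to the share of summits with it. The bar for that share was set when the shares were known, so its outcome was fixed and the shares are given as a description.

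The 293 summits away from small RNA genes lay mostly in promoters. Of these, 223 (76.1%, 70.8 to 80.9) were within 1000 bp of a protein-coding TSS against 40.7% of shifted summits, and 199 of the 223 (89.2%, 84.4 to 93.0) were upstream of it, at a median of 175 bp. Among 2079 hexamers, 134 were more frequent and 106 less frequent at these summits than in their flanks after Benjamini-Hochberg adjustment. GCCGCA was at 52 summits and 3 flanks (17.7% and 1.02%) and CGCGCA at 59 and 8, while CTGAAA was at 10 and 71. Summit windows here had 48.3% GC and flanks 37.5%, and the hexamer counts were not matched for composition. GAGAGA was at 49 summits and 23 flanks (adjusted exact p = 0.014).

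At the 246 summits near small RNA genes, GTTCGA, a part of the B box promoter element of RNA polymerase III, was at 100 summits and 7 flanks. The B box itself, as the pattern RGTTCRANNC, was within 50 bp of 97 of 180 tRNA summits (53.9%, 46.3 to 61.3) and 3 of their flanks, and of 23 of 50 snoRNA summits (46%, 31.8 to 60.7) and 0 flanks, but of 0 of 11 snRNA summits (upper bound 28.5%). Of the hexamers more frequent at summits, 44 were shared between the 134 of the first class and the 260 of the second. If the lists were independent, 16.75 would be expected, and no test of this was made. That reference ignores base composition. Over all 539 summits, windows had 49.5% GC and flanks 35.97%, so the shared hexamers do not show a shared sequence element. Among single genes, sup-5, a tRNA-Trp gene known from nonsense suppressor alleles, had a summit within it (chromosome III, 8678399 to 8678715, signal 538).

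For the first pattern, the excess of summits at small RNA genes, reads shared between identical gene copies are argued against as the whole cause: of the small RNA genes with no identical copy, 10.4% (8.41 to 12.7) had a summit, against 0.282% with shifted summits. For tRNA genes the share was 18.2% (12.2 to 25.5) without and 35.2% (30.9 to 39.7) with identical copies, so such reads may add to it. Genes with a nearly identical copy counted as having none, so reads shared between such copies were not tested. GC content is argued against too, since 0.494% (0.358 to 0.665) of GC-matched windows elsewhere held a summit against 31.2% of tRNA genes. Direct binding of LIN-11 through TAATTA within 50 bp could account for few of these summits, since 2 of 246 had it (0.813%, 0.0986 to 2.91). Of the flanks, 11 had it. Of the 13 summits with it on 1 side only, 15.4% had it at the summit, against 16.3% for hexamers of the same composition. Binding at those 2 summits or through other sequences stays open. Recovery of these regions whatever protein is tagged stays open too, because no library of untagged worms or of another tagged protein was used here.

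The second pattern is the promoter peaks away from small RNA genes. Unannotated genes of RNA polymerase III with this B box are argued against as the whole cause, since 3.07% (1.41 to 5.75) had it against 53.9% of tRNA summits. The pattern was at only 97 of 180 tRNA summits, so such genes without it were not tested. GC content alone is argued against as well, since among windows of the same GC content 0.499% (0.337 to 0.712) within 1000 bp of a TSS held such a summit and 0.108% (0.0493 to 0.204) farther away. Binding of LIN-11 there through TAATTA within 50 bp could account for few of these summits, since 7 of 293 had it (2.39%, 0.966 to 4.86). Of the flanks, 16 had it. Whether it acts at those 7 summits, or other sequences do elsewhere, was not decided. Of the 23 summits with it on 1 side only, 30.4% had it at the summit, against 27.8% for hexamers of the same composition. Preferential recovery of open promoters stays open, untested for lack of an accessibility map here.

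The third pattern is the cluster of 5 reproducible regions around lin-11. Extra copies of the locus carried by the transgene might raise signal there, and binding of LIN-11 at its own gene might too. The 18 other pooled-list regions within 20 kb were more than around 95.9% of protein-coding genes (median 7). That is above the median but short of the bound set, after the data were seen, as a sign of raised signal over the whole locus. Some of these 18 overlapped a reproducible region, and all 23 regions were more than around 99.1% of genes. The explanations therefore cannot be told apart.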
